A study of Mus musculus with 15 samples.

How the data were processed

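The series holds 15 single Tomato+ cells from mouse inguinal white fat, 1 library per cell, made with a SMART-Seq v4 3' DE kit and Nextera XT according to the labels' protocols. Per the submitters' processing notes the tools were TopHat2 and Cufflinks and the genome build was GRCm38. Their versions and settings are not given in the sources used here. The table used holds 8446 rows and 15 cell columns. Each column was tied to its cell through the number that its name shares with the sample title. A further 18 columns had no name and no values, and no column with values of a sample was left unused.

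The table is named as FPKM, but its deposited values are on a log2 scale: they end at 13.69. Reading them as log2(FPKM + 1) gives a mean sum of 592948 FPKM per cell, and reading them as natural logarithms gives 12675749, far above the usual total of FPKM. The log2 base was therefore inferred from the values and is not written in the file. The sorted values of the columns were the same to within 0.0354 above a value of 0.2, so the authors' deposited log2 values had also been quantile-normalized over the 15 cells. No label records the logarithm, this normalization or the filter that left 8446 rows. The design, fixed with the gene lists before the data were examined, had assumed linear FPKM. Thresholds of 1 and 5 FPKM were applied as log2(FPKM + 1) of the same FPKM, and no further logarithm was taken.

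This processing affects the measurements. Quantile normalization fixes the number of rows at 1 FPKM or more (4369) and at 5 FPKM or more (3417) in every cell, and also the share of the 50 highest rows (27.9%). These numbers say nothing about differences between cells. Each cell counts 4369 of its 8446 rows as detected, so the detection of a gene in 8 or more cells does not by itself show broad expression. The top of the scale, 13.69, is likewise shared by all cells, so genes at 13.69 hold the top rank of their cells and need not have equal levels. The number of rows tied at a cell's lowest value still differs and was used as the measure of breadth. Rescaling each cell to a common total multiplies all cells by nearly the same factor, so that it moves the threshold and little else. Read counts and depth are unknown. Genes such as Dcn, Gsn, Sparc, Ly6a, Fth1 and Xist and the mitochondrial genes had no row in the table used, so a missing row was not read as missing expression. FPKM divides by transcript length, while a 3' kit yields reads that do not grow with length, so long genes are understated.

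Gene identifiers were matched to a reference table of gene names. Of the 8446 rows 8431 matched, and 8222 of these had the same symbol in the table. In 15 rows the symbol had been turned into a date, in 14 of them with a number 1 below that of the true symbol, and the identifiers were used in place of the symbols. The 8446 rows held 8441 distinct identifiers. Coordinates are those of GENCODE M21 on GRCm38. Multi-copy small RNAs, near-identical gene copies and overlapping genes are marked as uncertain, since no label states how shared reads were counted.

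The labels give 1 group and name no animal, so the cells are described one by one. No p-value, standard error or count of changed genes was computed from cells. Shares of cells have exact Clopper-Pearson 95% intervals. The 27 fixed gene lists were: Prrx genes, housekeeping, stromal progenitor, Dpp4 progenitor, committed preadipocyte, Cd142 stromal, adipogenic transcription factors, mature adipocyte, thermogenic, endothelial, mural, immune, mesothelial, epithelial, Schwann, skeletal muscle, erythroid, bone and cartilage, marrow stromal and mesenchymal stem cell, cell cycle, immediate early and heat shock, inflammatory, complement, ECM remodelling, signalling receptors, skin and dermal fibroblast, and sex-linked. Of their 310 distinct genes 183 had a row. A list's level is the median over its genes of the mean value over cells, given as a percentile among 10000 random lists of the same size from the 8022 genes detected in at least 2 cells, for the 17 lists with at least 3 genes. A list's covariation is the mean Spearman correlation over its gene pairs, for genes detected in at least 3 cells, given as a percentile among 10000 random lists drawn from the 100 genes nearest in mean value, out of 7425 genes, for the 15 lists with at least 4 such genes. Correlations between lists were treated in the same way, and of these only that of the Dpp4 and preadipocyte lists was fixed in advance. The random lists do not hold together as the real ones do, so percentiles between lists can look more extreme than 15 cells allow. This step was not simulated. Genes named by the rule fixed in advance were Prrx1, the 2 to 4 members of each list detected in most cells, the highest detected member of each list of another cell type, the 20 genes highest by median with ribosomal, mitochondrial and predicted genes left out, and 15 genes with the largest spread above the running median of 100 genes of similar mean. These 15 had to be detected in 5 to 12 cells and to reach 100 FPKM in 1 cell. Other list members could be named with their number of cells, and which of their values in single cells to print was decided after the values were seen. The further mitosis genes and the genes of single cells in the closing observations were also chosen after their values were seen.

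The covariation step was tested on simulated data over 7425 genes, made by permuting the values of each gene over the cells, which removes the correlation between genes. Of 100 simulated 12-gene lists with no shared shift 6% lay above the 95th percentile. With a shared shift of 1 log2 in 5 cells 81% did, and with shifts of 2 and 4 log2 all did. The rate without a shift lies near its nominal value by construction. The other rates hold for a background without correlation, unlike that of the real cells. Also recomputed, as fixed in advance, were other detection thresholds, rescaling, a pseudocount of 0.1 in place of 1, all rows as the background, Pearson correlation, genes detected in 5 to 15 cells, and leaving out the 3 cells with the fewest genes above their lowest value. Chosen after the data were seen were leaving out cell 13 or cells 5 and 13, multiplying the length back, and asking for 1% of a gene's highest cell. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed 7.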

Results

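Single cells carrying the Tomato reporter were profiled from the inguinal white fat of adult C57BL/6 mice. In these mice a tamoxifen-activated Cre recombinase under the control of Prrx1 switches on Tomato. Prrx1 encodes a homeobox transcription factor of the limb and skeletal mesenchyme. The mice received 2 mg of tamoxifen per 30 g of body weight once a day for 3 days. Minced fat was digested with collagenase II at 2 mg/ml for 1 h at 37 °C, passed through 70 µm and 40 µm strainers and sorted for Tomato, and single cells were then picked under a fluorescence microscope. The question addressed was which cells of this fat depot the Prrx1 reporter marks and what they express. The 15 cells form 1 group and are numbered 1 to 15. The labels name no animal, so the cells share an unknown number of mice, the group counts as 1 sample, and no p-value is given. Values are log2(FPKM + 1) throughout unless a percentage or a count is named, and a gene was counted as detected at 1 FPKM or more. Intervals on shares of cells are exact binomial 95% intervals and cover counting error only.

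Housekeeping genes were detected in nearly every cell, with exceptions among the lower ones. Between 930 and 1974 genes stood at the lowest value of a cell, with a median of 1385, and 4369 reached 1 FPKM in each cell because the values had been brought to a common distribution. Read depth is unknown, since the values hold no counts. Of the 14 housekeeping genes with a row, 10 were detected in all 15 cells, among them Actb (median 10.01), Eef1a1 (10.49) and Ppia (9.96). Hprt, Pgk1 and Tubb5 were each detected in 14 cells. Tbp, the TATA-box binding protein that every cell uses, was detected in 3 cells only. A value near 0 of a low gene therefore cannot be read as absence. Spearman correlations between pairs of cells, taken across 8022 genes that are not independent replicates, ranged from 0.318 to 0.555 over the 105 pairs, with a median of 0.457. Cell 13 had the lowest median correlation with the other cells (0.387) and cell 7 the highest (0.491).

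Prrx1 was detected in 12 of 15 cells (80.0%, 95% interval 51.9% to 95.7%), with a median of 4.65. The gene (ENSMUSG00000026586) lies on the minus strand of chromosome 1, from 163245119 to 163313710 in GRCm38. Its highest value was 7.56 in cell 11, and it was below 1 FPKM in cells 3 (0.68), 12 (0.22) and 13 (0.43). At 5 FPKM or more, 10 cells remained. Prrx2, its close paralogue, was also detected in 12 cells, with its highest value in cell 6 (9.29). Neither gene was detected in cells 3 and 13. Cell 12 was below 1 FPKM for Prrx1 but had Prrx2 at 7.57. The reporter acts as a permanent mark after recombination, and the Tomato transcript itself was not analysed here.

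**Figure D1:**
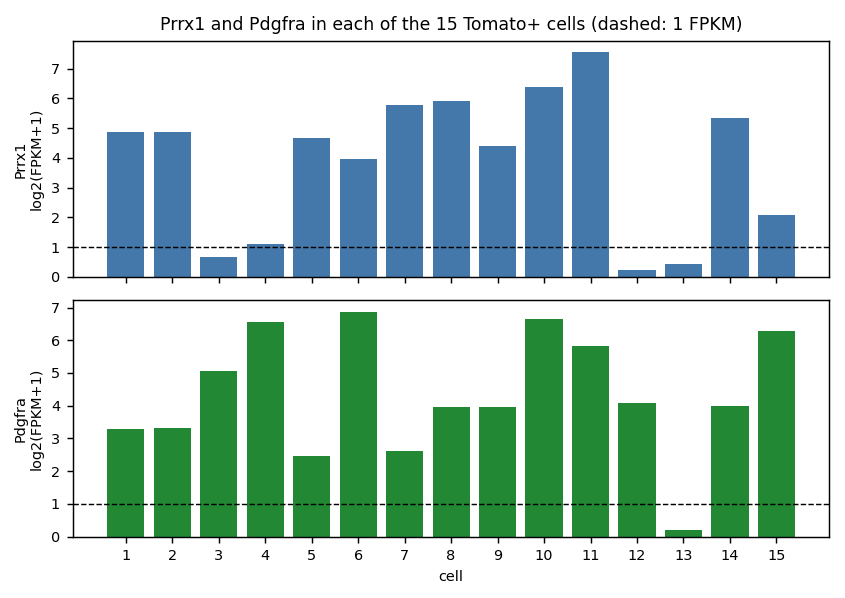
Prrx1 (top) and Pdgfra (bottom) in each of the 15 cells, as log2(FPKM + 1) on the vertical axis, with 1 bar per cell and a dashed line at 1 FPKM. Prrx1 passes the line in 12 cells and Pdgfra in 14, and cell 13 is below it for both.

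The Tomato+ cells carried a fibroblast and stromal progenitor profile. All 16 analysed genes of the stromal progenitor list were detected in at least 13 cells, and 12 of them in all 15 cells. Collagen genes led the list, with medians of 11.49 for Col3a1 and 10.64 for Col1a2, followed by the complement inhibitor Serping1 (10.44), the filament protein Vim (10.41) and the proteoglycan Lum (10.24). Pdgfra, the receptor that marks fibroblastic progenitors of fat, was detected in 14 of 15 cells (93.3%, 95% interval 68.1% to 99.8%), from 2.48 to 6.88 in these, and stood at 0.20 in cell 13. Cd34, a surface marker of fat progenitors, was detected in all 15 cells (95% interval from 78.2% of cells) with a median of 7.87. Pdgfrb was detected in 13 cells, with its highest value in cell 13 (7.66). The list's median of gene means was 8.08, above all of 10000 random lists of 16 genes, and its genes went together from cell to cell (mean pairwise Spearman correlation 0.175, percentile 99.99 among matched random lists). These percentiles describe these libraries. Cell 11 had the highest mean of the list (9.05), and cells 12 (5.94) and 13 (5.67) the lowest. Ly6a, Dcn, Gsn and Sparc were not analysed here.

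The 20 genes highest by median were Ubb, B2m, S100a10, Mt2, Lgals1, Pcolce, Ecm1, Cd63, Col3a1, Cst3, S100a4, Serpinf1, Gpx3, S100a11, Ifitm3, Ftl1, Plac9b, Txnip, Dynll1 and Itm2b, after 3 ribosomal protein genes were left out. Pcolce, which enhances collagen processing, had a median of 11.64, and Serpinf1, the secreted pigment epithelium-derived factor, had a median of 11.30 with a lowest value of 1.32. All 20 were detected in each cell. Plac9b has a near-identical copy, Plac9a, so its value is uncertain. Short genes are favoured, since FPKM divides by length while the library kit reads the 3' end: the 20 genes had a median longest transcript of 1269.5 nt against 3264 nt for all genes, and 11 of the 20 stayed among the highest when the length was multiplied back. Col1a2 and Vim then entered.

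Within the stromal profile, genes of the Dpp4 progenitor list tended to be high where genes of the committed preadipocyte list were low. Dpp4+ interstitial progenitors and Icam1+ committed preadipocytes are 2 described stages of the fat lineage. Dpp4 was high in cell 1 (7.93) and cell 7 (6.87), and at most 2.24 in the other 13 cells. The same 2 cells had the highest values of Sema3c (7.11 and 5.80), Cd55 (9.02 and 6.35) and Anxa3 (11.20 and 11.03). Fabp4, a fatty acid carrier of differentiating adipocytes, stood at 6.00 in cell 1 and 6.29 in cell 7. It was lower still in cells 9 (1.24) and 11 (4.95), where Dpp4 was low too, and highest in cells 4 and 13. Both stood at 13.69, the top of the scale that the normalization gives every cell, so their equality carries no meaning. Of these 2 cells, cell 13 detected 11 of the 18 preadipocyte genes, as few as cells 1 and 8.

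Of the Dpp4 list, 18 genes were analysed, 10 were detected in 8 or more cells, and Wnt2 was detected in none. The list's level stood at percentile 26.58 among random lists. Dpp4 itself (chromosome 2, 62330073 to 62412231) was detected in 5 of 15 cells (33.3%, 95% interval 11.8% to 61.6%) and Pi16, another marker of this stage, in 4, with 5.12 in cell 2 and 3.53 in cell 1. Anxa3 was detected in all 15 cells, and Cd55, Fn1, Ugdh and Cd248 in 14. The list's mean was 5.38 in cell 1 and 4.16 in cell 7, and between 0.96 and 3.53 in the other cells. All 18 genes of the committed preadipocyte list were analysed, and 7 were detected in all 15 cells: Sparcl1 (median 9.45), Fabp4 (9.06), Bgn (8.19), Col4a1 (7.91), Lpl (7.74), Col4a2 (7.47) and Apoe (6.40). Lpl encodes the lipoprotein lipase. Pparg, the master regulator of adipocyte differentiation, was detected in 7 cells (46.7%, 95% interval 21.3% to 73.4%), with 9.29 in cell 13, 6.25 in cell 14, 5.78 in cell 6 and 5.50 in cell 12. Icam1 was detected in 6 cells, highest in cell 15 (7.31), and Dlk1, which holds preadipocytes undifferentiated, in 6, highest in cell 9 (8.24). The list's mean ranged from 3.05 in cell 1 to 7.22 in cell 6.

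Each list held together. The mean pairwise correlation was 0.184 for the Dpp4 list and 0.188 for the preadipocyte list, both above all of 10000 matched random lists. Across the lists it was −0.110, below all 10000 pairs of random lists. Without cells 1, 11 and 14, which have the fewest genes above their lowest value, it was −0.0597 at percentile 0.16, so part of its size rested on these cells, cell 1 among them.

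The Cd142 list marks another stromal population of fat. F3, which encodes Cd142 or tissue factor, was detected in 14 of 15 cells (93.3%, 95% interval 68.1% to 99.8%), and Mgp, an inhibitor of calcification, in 14, with 13.69 in cell 8. The more selective members were narrower. Clec11a was detected in 5 cells, with 7.41 in cell 2 and 4.83 in cell 8, and Fmo2 in 8 cells, with 8.70 and 8.32 in the same 2 cells. Gdf10 was also highest in cells 2 (8.69), 8 (8.03) and 14 (6.91). The 10 analysed genes had a mean correlation of 0.150 (percentile 99.78), and of 0.0981 with the Dpp4 list (percentile 100). Both rested on cell 13, which detected 1 gene of the Cd142 list: without it the correlations were 0.0263 (percentile 76.37) and 0.0268 (88.9). The preadipocyte and Cd142 lists had a mean correlation of −0.0289 at percentile 7.27, and of −0.0673 at percentile 0.1 without cell 13.

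**Figure D2:**
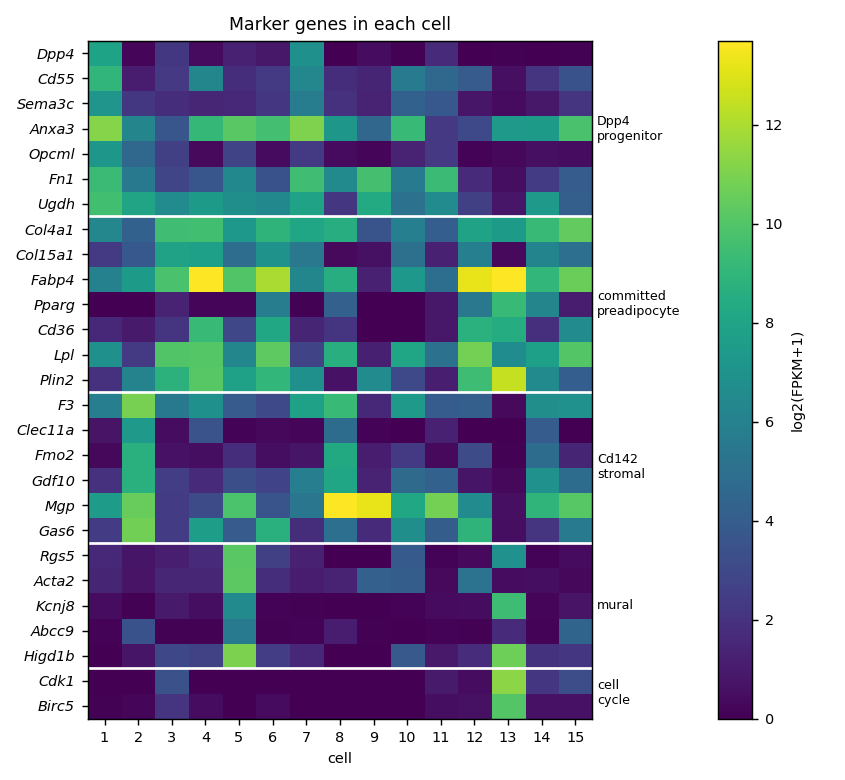
Values of genes from the Dpp4 progenitor, committed preadipocyte, Cd142 stromal, mural and cell cycle lists (vertical axis) in each of the 15 cells (horizontal axis), with colour giving log2(FPKM + 1). Dpp4 is at 7.93 in cell 1 and 6.87 in cell 7, Clec11a and Fmo2 are highest in cell 2, and Rgs5 and Higd1b are highest in cells 5 and 13.

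Several adipogenic transcription factors were detected widely, while genes of mature adipocytes were detected in few cells. Ebf1 and Klf4 were detected in all 15 cells (medians 5.94 and 5.99), Cebpd in 14 (6.53), and Cebpb and Ebf2 in 13 each. Cell 12 detected all 12 analysed adipogenic transcription factors, while the other cells detected 5 to 9. Zfp423, a factor of preadipocyte commitment, was detected in 5 cells, highest in cell 10 (6.38). The list's level stood at percentile 86.0 among random lists, and its correlation did not pass the 95th. Of the mature adipocyte list, 5 genes were analysed and none was detected in 8 or more cells. Scd1, a fatty acid desaturase, was detected in 7 cells, Pnpla2, a triglyceride lipase, in 4, the synthase Fasn in 4, Cfd in 4 and Acaca in 3. Cell 12 had the highest Pnpla2 (7.50) and Scd1 (7.05), and cell 5 the highest Acaca. The list's level was at percentile 9.32, and its correlation did not pass the 95th. Of the thermogenic list, Cox7a1 was detected in 2 cells and Tmem26 in none. Adipoq, Plin1, Lep and Ucp1 were not analysed here.

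Of the lists for other cell types, the mural list, with 5 genes analysed, was high in 2 cells. Mural cells are the pericytes and smooth muscle cells around vessels. In cell 5, Higd1b stood at 10.98, Rgs5 at 10.18, the smooth muscle actin Acta2 at 10.23, and the potassium channel genes Kcnj8 and Abcc9 at 6.53 and 5.68. In cell 13, Higd1b stood at 10.68, Kcnj8 at 9.43 and Rgs5 at 6.90, while Abcc9 was at 1.68, below cells 2 and 15, and Acta2 at 0.45. The list's mean was 8.72 in cell 5 and 5.83 in cell 13, and at most 2.37 elsewhere. Cell 5 also carried stromal genes (Prrx1 4.65, Pdgfra 2.48, Col1a2 8.24). Cell 13 detected 14 of the 16 stromal progenitor genes, among them Col3a1 (8.25, above 7.40 in cell 5), Col6a1 (8.06), Vim (12.02) and Pdgfrb (7.66), but not Pdgfra and Mmp2. Mmp2 stood at 0.73 there, where the lowest of the other cells was 6.58.

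Of the 14 fixed cell cycle genes 4 were analysed, and 2 of them were highest in cell 13. Cdk1, the kinase that drives entry into mitosis, stood at 11.34 in cell 13, and Birc5, a chromosomal passenger protein, at 10.04. Cells 3 and 13 detected all 4. Of 36 further mitosis genes, chosen after values were seen, 19 were analysed, so their count describes the choice as well as the cells: 18 were highest in cell 13 and all 19 reached 5 FPKM there, among them Ube2c (11.75) and Prc1 (11.37). At 1 FPKM cell 15 detected 15 of them, cell 3 detected 13, and cells 12 and 14 detected 8 each. At 5 FPKM cell 15 had 10, and the other cells at most 5. Pcna, which also takes part in DNA repair, was detected in 14 cells and was highest in cell 15 (7.82, against 4.39 in cell 13), and Tyms, a thymidylate synthase, in 7, highest in cell 12 (7.05, against 5.55).

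Some mural genes passed 1 FPKM in further cells at low values. Rgs5 was detected in 8 cells (53.3%, 95% interval 26.6% to 78.7%) and Higd1b in 10, but when a cell also had to reach 1% of the gene's highest value, 3 cells remained for Rgs5, 2 for Higd1b, and 4 for Acta2. The mural list's correlation of 0.228 (percentile 98.86) was 0.125 (84.58) without cell 13 and −0.0946 (21.11) without cells 5 and 13. With genes detected in 5 or more cells it was 0.131 (87.58), and as a Pearson correlation, which weighs the high values of single cells, 0.595 (100). Its mean correlation with the stromal progenitor list was −0.114 (percentile 0.08), but −0.0593 (5.7) without cell 13 and 0.0029 (52.71) without cells 5 and 13. With the preadipocyte list it was 0.0817 (99.53), and 0.092 (99.42) without cells 5 and 13. With the Dpp4 list it was −0.0327 (14.48), and 0.0487 (90.08) without these cells.

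Few markers of blood, vessel lining and nerve were analysed, and most stood low. Of the endothelial list, Tek was detected in 1 cell (cell 1, 5.04) and Esam, which pericytes also carry, in 7 cells, highest in cell 13 (10.90), of which 2 reached 1% of that value. Csf1r, a receptor of macrophages, was the 1 analysed gene of the immune list and was detected in 4 cells, highest in cell 2 (6.39). Of the Schwann list, Mbp was detected in 13 cells at up to 5.02, and S100b in 6 at up to 6.07. Alas2, the erythroid enzyme of heme synthesis, was detected in 14 cells at up to 5.12. It lies inside Apex2 on the opposite strand, and reads of the pair may not have been told apart. No gene of the mesothelial, epithelial and skeletal muscle lists was analysed here, and the endothelial and immune lists rest on 2 genes and 1 gene.

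**Figure D3:**
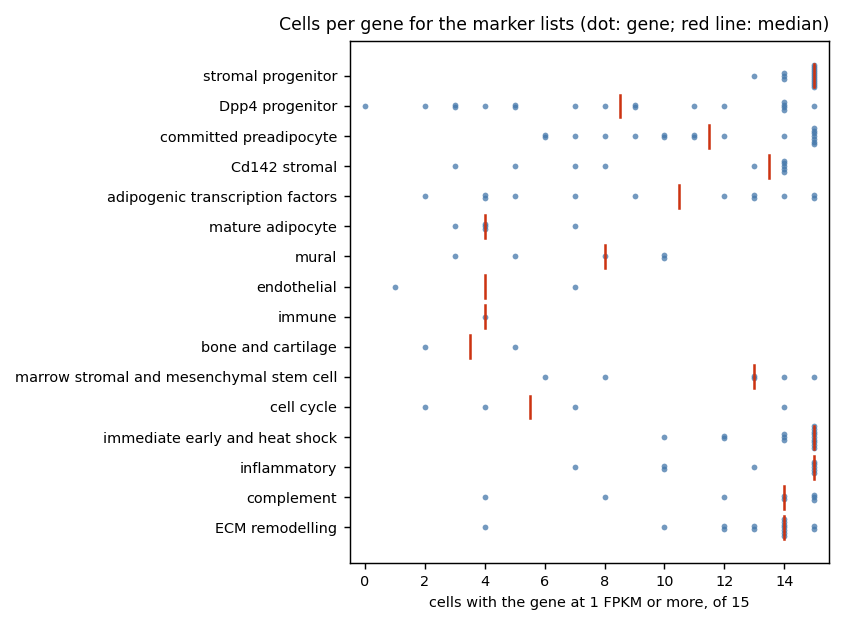
Number of the 15 cells with each gene at 1 FPKM or more (horizontal axis) for 16 marker lists (vertical axis), with 1 dot per analysed gene and a red line at the list's median. The stromal progenitor and immediate early lists have a median of 15 cells, and the mature adipocyte list a median of 4.

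Markers of skeletal and marrow stroma were mixed. Prrx1 also marks bone and marrow mesenchyme, which is the reason for these lists. Cxcl12, the chemokine of marrow reticular cells, was detected in 14 of 15 cells (93.3%, 95% interval 68.1% to 99.8%) with a median of 7.59. Itgav was detected in all 15 cells, Cd44 and Vcam1 in 13 each, Kitl in 8 and Eng in 6. The 6 analysed genes of this list had a level at percentile 85.98, and their correlation did not pass the 95th. Of the bone and cartilage list, Alpl, the bone-type alkaline phosphatase, was detected in 5 cells, highest in cell 3 (5.71), and Sox9 in 2. Of the skin and dermal fibroblast list, Dpt was detected in all 15 cells (median 8.65) and Sfrp4, a Wnt-binding protein, in 14. Sfrp2 was detected in 8 cells, highest in cell 2 (10.19), Twist2 in 7, and En1, which marks a dorsal dermal fibroblast lineage, in 3. The 7 analysed genes had a mean correlation of 0.148 (percentile 98.17), which was 0.0309 (70.81) without cell 13.

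Immediate early genes were detected in most cells, and the heat shock genes of the same list stood lower. All 15 genes of that list were analysed and detected in 10 or more cells, and 9 were detected in all 15. Fos had a median of 10.75, Dusp1 of 8.23, Egr1 of 7.96 and Ier2 of 7.93. The list's level and its mean correlation of 0.498 lay above all of 10000 random lists, and without cells 1, 11 and 14 the correlation was 0.330 (percentile 100). Of the 15 lists tested for correlation, 11 passed the 95th percentile, and 8 did without cell 13. Cell 14 had the highest mean (7.98) and cell 11 the lowest (2.85), with Egr1 at 1.39 and Ier2 at 1.88. All cells were digested at 37 °C, so the level in undigested tissue cannot be read. The heat shock genes Hspa1a and Hspa1b, which are near-identical, were detected in 10 and 12 cells (medians 2.02 and 2.54) and were highest in cell 8 (8.75 and 8.54), and their separate values are uncertain.

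Cytokine, complement and matrix genes varied between cells as groups. Of 9 analysed inflammatory genes 5 were detected in all 15 cells. Cxcl1, a neutrophil chemokine, had a median of 9.24, and Ccl2, a monocyte chemokine, was highest in cell 9 (13.69). The list's mean was highest in cell 15 (8.29). Of 8 complement genes, Serping1, C1s1 and C3 were detected in all 15 cells. C3, the central component, ranged from 2.15 in cell 13 to 11.75 in cell 10, and C4b from 0.91 to 12.27. The complement genes had a mean correlation of 0.385 and the inflammatory genes of 0.223, at percentiles 100 and 99.98. Cell 13 stood apart on the complement list, with the lowest mean (1.80) and 6 of the 8 genes below all other cells. Of 15 matrix remodelling genes 14 were detected in 8 or more cells. Fbln2, an elastic fibre protein, had a median of 8.46, and the protease inhibitor Timp2 of 7.68. The list's mean correlation was 0.167 (percentile 100), and 0.107 (99.75) without cells 5 and 13. Postn, a matrix protein of remodelling tissue, was above 11 in cells 9 (12.98), 11 (11.88) and 13 (11.58) and at most 6.46 in the others.

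Of 13 analysed receptors 7 were detected in 8 or more cells. Tgfbr2 was detected in all 15 cells (median 5.37), and Egfr (6.19) and Fgfr1 (5.14) in 14 each. The oestrogen receptor Esr1 was detected in 7 cells. The list's mean correlation was 0.17 (percentile 100). Long receptor transcripts are understated by FPKM from 3' reads.

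Genes with the largest cell-to-cell spread were partly small noncoding RNAs. Among 1620 genes detected in 5 to 12 cells with a highest value of at least 100 FPKM, the 15 with the largest excess spread were Rny3, Vaultrc5, Nudc, Vps36, Zfp865, Rnu3a, Rnu5g, Lbhd1, Rpph1, Mrpl2, Adm, Tmem219, Trf, Cd200 and Nsun6. Rny3, a Y RNA, reached 13.69 in cell 5 and was below 0.001 in 3 cells. Adm, the vasodilator adrenomedullin, was above 7 in 7 cells, with 9.35 in cell 6 and below 0.001 in cell 13. Trf, the iron carrier transferrin, reached 10.96 in cell 3 and 10.26 in cell 12, and Cd200, an immune-modulating surface protein, 12.36 in cell 5. Rnu3a, Rnu5g and similar RNAs exist in many copies, so their values are uncertain.

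Of the sex-linked list 4 genes were analysed, all on the Y chromosome, and 2 of them were detected in 8 or more cells. Ddx3y and Eif2s3y were each detected in 13 cells, Kdm5d in 5 and Uty in 1. The labels state no sex to set this against.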

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

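Leaving out cell 13 or cells 5 and 13, multiplying by length and asking for 1% of the highest cell, and all list pairs but that of Dpp4 and preadipocyte genes, were chosen only after the results were seen. Of 406 values recomputed for 76 results, 349 were labelled as kept and 57 were not, under a lenient rule. Cell counts that stayed inside their wide intervals were kept, such as Dpp4 from 5 to 2 and Rgs5 from 8 to 4 at 5 FPKM. Also kept were the Dpp4 and mural lists, from −0.0327 to 0.0487 without cells 5 and 13. The preadipocyte and Cd142 lists were kept too, from percentile 7.27 to 0.1 without cell 13. The 1 result labelled reversed was the stromal and mural lists, from −0.114 to 0.0029 without cells 5 and 13. That value, at percentile 52.71, is a lost correlation and not one of opposite sign. With any value above a cell's lowest counted as detected, the median number of detected genes was 7061 and Prrx1 was counted in 15 cells; this setting has almost no lower limit and gave 24 of the 57 changes, all to more cells or genes. Weaker correlations, of the Cd142, mural and skin lists, numbered 5 without cell 13 and 4 without cells 5 and 13. At 5 FPKM Prrx1 was counted in 10 cells, after rescaling in 13, and with 1% of the highest cell required in 11. The share of the 50 highest genes was 29.5% with ribosomal protein genes left out first and 24.2% with the length multiplied back, where the genes that enter the sums differ by construction. Of the 15 genes of largest spread, 8 were shared when cells 5 and 13 were left out; the cause was not tested. The number of lists whose genes went together was 11, and 8 without cell 13. The negative correlation of the Dpp4 and preadipocyte lists ranged from −0.151 to −0.0597 over its alternatives, at percentile 0.16 or lower. Depth is unknown, so the detection of low genes such as Tbp limits every count of cells. No paired analysis was possible because the cells form 1 group.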

Other observations

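All tests and their bounds below were chosen only after the result was seen, and the test of cells 5 and 13 was revised 2 times on seeing its outcome. Its first form took the median difference of the stromal genes from the other cells (−3.32 in cell 13, −1.57 in cell 5) with an error over genes, and was dropped because cell 12, with a mural list mean of 1.57, also stood at −1.95. The second counted cell 13 among the cells that cell 5 was set against and labelled a mixture in cell 5 as fitting, and the form given here leaves cell 13 out. The bounds for shared reads were set with the ratios in view and later made stricter by the level in cells without cell cycle genes, and a pattern of immediate early genes was set aside unweighed.

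Single cells had very high values of genes that mostly lie outside the fixed lists. Cell 9 had Mest at 11.58, where the next highest cell had 4.42, and C1qtnf3 at 9.59 against 0.94 in the next, together with Dlk1 at 8.24, Postn at 12.98 and Tnc, a matrix protein of growing tissue, at 7.73. Mest and Dlk1 are imprinted genes. Cell 12 had Car3, the carbonic anhydrase of adipocytes and muscle, at 12.98 against 7.09 in the next cell, Nnat at 11.17 against 4.19, and Pnpla2 at 7.50 against 2.20. Nnat and Snurf (9.06 in cell 12, next 4.09) are also imprinted. Cell 2 had Sfrp2 at 10.19 against 5.54, beside Clu at 11.20, and cell 10 had Myoc at 9.90 against 4.29. These genes were picked by their values.

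Cells 5 and 13 carried mural genes. A mural and a stromal cell in 1 well, each giving an equal share of the RNA, was tested through the 16 stromal progenitor genes, which should then lie no more than 1 log2 below the lowest of the other cells. In cell 13, 7 genes lay lower than that, against at most 2 in the 13 other cells, which argues against equal shares there. A mixture in cell 13 with a smaller stromal share was not tested and stays open. In cell 5, 1 gene did, and 9 of the 13 other cells had 0, so a mixture and a cell with both programmes cannot be told apart. Cell 13 was sorted and picked by Tomato like the others, and its Prrx1 of 0.43 does not set it apart from cells 3 (0.68) and 12 (0.22), so a cell picked without the reporter can be neither shown nor excluded without Tomato, which was not analysed here, and no biological explanation was tested.

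Prrx1 and the preadipocyte list were set against each other after their values in these same cells had been seen, so the numbers describe the cells and are no independent test. The mean rank correlation of Prrx1 with the 18 genes was −0.259 (14 genes negative), at percentile 3.1 among 1000 genes of similar mean, and missed the bound of 2.5. Without cell 13 it was −0.339 at percentile 1.0, and without cells 5 and 13 it stood at 1.1. Leaving out cell 13 made the correlation more negative, with 15 genes negative, which argues against cell 13 as its source in these cells. Whether Prrx1 goes down as the list goes up stays open.

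Of the genes private to cell 13, at 6 or more there and at least 2.5 above the next cell, 18 cell cycle genes stood at a median of 0.247% of their value there in cell 3, 0.311% in cell 15, 0.117% in cell 14 and 0.107% in cell 12, and the 45 others at 0.229%, 0.187%, 0.0548% and 0.143%. These are the 4 cells with the cell cycle genes above 0.05%, and cell 11 lay at that limit with the others at 0.0669%. The ratio of the second to the first was 0.467 or more in the 4 cells, with a median of 0.763, but cell 8 had the 45 others at 0.0939% with the cell cycle genes at 0, above the level in cell 14 (as it was in cell 11), so the ratios decide neither for reads of cell 13 assigned to other libraries nor against cycling of these cells. Over the 499 private genes of all cells, 20 of 210 ordered pairs of cells lay in the top 2.5% of random lists, where such lists give 5.25. Among them were the genes of cell 13 in cells 3 (percentile 99.98), 12 (99.68) and 15 (100) but not in cell 14 (93.96), and 8 of the 20 had their mirrored pair among them. Other pairs lay at the opposite end, such as the genes of cell 13 in cells 5 (0.03) and 7 (0.0) and those of cell 5 in cell 8 (0.0). Pairs of cells thus spread beyond the random lists at both ends, and the excess of 20 over 5.25 does not by itself show sharing. The labels give no pools or lanes, so both explanations stay open, and counts of cells at 1 FPKM may include shared reads for genes very high in 1 cell.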
